A study of Arabidopsis thaliana with 6 samples.

How the data were processed

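RNA was extracted from whole seedlings aged 12 days, grown at 22 °C under 100 µmol of light per square metre and second on medium with 1% sucrose and 1% agar, per the labels' protocols. The libraries were made with a directional kit, which keeps the strand of the RNA. The deposited table holds raw counts per gene identifier, with a column for each of the 6 libraries. Per the submitters' processing notes, the tools were CASAVA 1.4, STAR 2.5.3a and StringTie 1.3.3b, and the genome build was TAIR10. Which of these gave the counts, the strand setting, the annotation and the way RNA was selected are not given in the sources used here.

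The deposited counts came in 27080 rows. Identifiers with 6 digits in place of 5 numbered 280, and all 280 held the same counts as the row of their first 5 digits, so they were left out, which removed 0.748% to 1.1% of each library. Of the 26800 remaining identifiers, 26505 matched a locus tag of the RefSeq annotation of TAIR10.1, which gave symbols and coordinates. The counts carry no coordinates, so none were taken from them. Total counts ranged from 43019056 to 64938734, and 1 count was worth 0.0155 to 0.0234 CPM. No 2 libraries of a group were copies of one another, since chi-square per degree of freedom between pairs was 122 to 146.

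The 3 libraries labelled vih1vih2 were compared with the 3 labelled wild type in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with default settings (22818 tested), scaled by TMM and tested by the quasi-likelihood method (glmQLFit and glmQLFTest) with group as the only term. Calls were made at a Benjamini-Hochberg adjusted p under 0.05. The standard error is the absolute log2 fold change divided by the square root of the F statistic. For a gene with no count in 1 group the fold is a bound, set against 3 counts over that group. Such bounds cover counting error only, and not counts lost from an identifier. Gene lists (29, holding 417 entries, of which 406 had a row and 381 were tested) were fixed before the data were examined. All but the list of the targeted genes were tested with camera (limma 3.58.1), with a preset correlation of 0.01 and with an estimated one, adjusted over 28 lists. Fry, which tests whether a list's genes move on balance one way without setting them against other genes, was run as well. The 11 entries without a row were not analysed here.

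Named genes followed a rule fixed before the data were examined. It took VIH1 and VIH2, the 8 genes with the largest fitted change each way among called genes of at least 5 CPM whose groups did not overlap, and the called members of largest change in each list with at least 1 CPM. From each Pi starvation list it took up to 6 called members and the best-expressed members not called, and it allowed every Pi regulator. Some examples in the text (AT4, PHT1;1, PHT1;4, SQD1, SQD2, MYB75, LOX2, VSP2 and EGL3, and in the closing section SAUR22, SAM1 and the genes flanking VIH1 and VIH2) fall outside it and were chosen after their values were seen.

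The fit was tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold. A first simulation, drawn with edgeR's shrunken dispersions, recovered 1% of the 2-fold and 72% of the 4-fold changes among 21967 genes fitted. A second dispersion model, taken by moments from the spread within groups, was added after that result was seen. It recovered 40% of the 2-fold and 78% of the 4-fold changes among 22033 genes fitted, with none of wrong sign and 4 of the 21833 unchanged genes among them called. Neither model is known to match the real spread. Each simulation changed 200 genes, where 9324 were called in the real data, so its Benjamini-Hochberg cut-off on the unadjusted p was stricter. The shares recovered therefore do not carry over to the real fit, where changes of about 2-fold may still be missed.

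The alternatives fixed before the data were examined were DESeq2's size factors, the DESeq2 1.42.0 Wald test, limma-voom, no filter, a filter of 5 CPM in 3 libraries, each library left out, the replicate number as a block, plastid, mitochondrial and rRNA genes removed, a threshold of 0.01, glmTreat against 1.5-fold, and other sizes of the group of most counted genes. Added after the data were seen were copied rows collapsed, the malformed rows kept, genes with a gap removed, and robust moderation. A gap is a library at least 16-fold below both others of its group, which lie within 2-fold of each other at 5 CPM or more. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.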

Results

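Transcript counts per gene were deposited for 6 libraries from whole Arabidopsis thaliana seedlings aged 12 days. Of these, 3 are labelled wild type (the Col-0 accession) and 3 are labelled vih1vih2, a double mutant of VIH1 and VIH2, which encode the kinases that make the inositol pyrophosphate InsP8. The series title presents InsP8 as a signal of the phosphate (Pi) status inside the cell, so the comparison asks how the transcriptome of the double mutant differs from wild type. Total counts were 64938734, 49563213 and 43019056 in the libraries labelled wild type and 53492430, 48343531 and 51080266 in those labelled vih1vih2. Below, each CPM is the TMM-scaled mean ± SD of n = 3 libraries, and each log2 fold change is the libraries labelled vih1vih2 over those labelled wild type, ± its standard error. "Rose" and "fell" are used of genes called by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05.

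The targeted genes did not bear out the labels, since both had more counts in the libraries labelled vih1vih2. VIH2 (AT3G01310, chromosome 3, 93995 to 102010 on the minus strand of TAIR10.1) had 2759, 2783 and 2310 counts in the libraries labelled wild type and 33783, 35310 and 38660 in those labelled vih1vih2. Its log2 fold change was 3.64 ± 0.14, with an adjusted p of 3.74e-05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. VIH1 (AT5G15070, chromosome 5, 4876515 to 4885836 on the plus strand) had 325, 361 and 246 counts against 1737, 1524 and 1820, a log2 fold change of 2.31 ± 0.16. Only 1 stretch of 50 bases was shared between the 4266 in spliced VIH1 transcripts and the 3933 in those of VIH2. Gene-level counts do not show whether a transcript is intact, and the position of the insertions was not given in the sources used here. The counts of these 2 genes therefore do not contradict the labels either. Every direction below rests on labels that these 2 genes did not bear out.

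**Figure D1:**
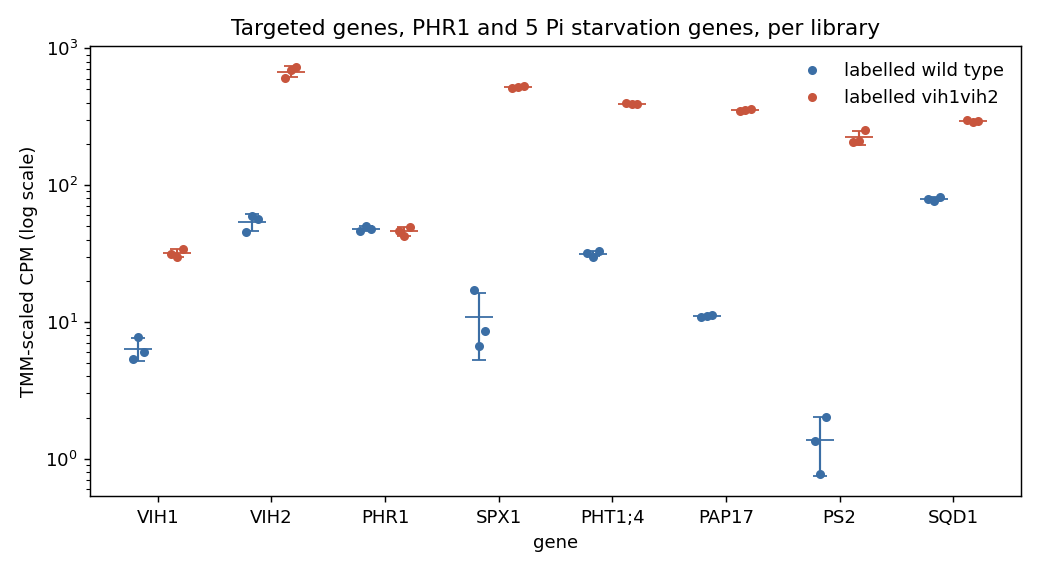
TMM-scaled CPM on a log axis for VIH1, VIH2, PHR1 and 5 Pi starvation genes, with a point for each of the 3 libraries per group, a horizontal bar for the mean and whiskers for 1 SD. VIH2 averaged 54.0 CPM in the libraries labelled wild type and 676 in those labelled vih1vih2, and PHR1 averaged 48.2 and 46.2.

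Genes known to be induced by Pi starvation were higher in the libraries labelled vih1vih2. Of the 42 tested members of the 3 Pi starvation lists, 40 rose, and 41 did when adjusted over the list alone. SPX1, a Pi sensor protein, went from 10.8 ± 5.54 to 521 ± 7.60 CPM, a log2 fold change of 5.59 ± 0.43. The purple acid phosphatase PAP17 went from 11.1 ± 0.247 to 356 ± 5.06 CPM. The phosphatase PS2 went from 1.38 ± 0.631 to 224 ± 25.7 CPM.

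Among 20 tested genes of Pi transport and signalling, 19 rose, both over all genes and adjusted over the list alone, with a median log2 fold change of 3.23. The non-coding RNA IPS1, which sequesters the microRNA miR399, was 562-fold higher, with 8, 15 and 0 counts in the libraries labelled wild type, and 1279-fold or 374-fold higher without wild type 2 or 3. The related AT4 was 34.5-fold higher. The Pi transporters PHT1;4 and PHT1;5 were 12.5-fold and 46.2-fold higher. PHT1;1, which has near-identical paralogs between which the counting could split reads, had a log2 fold change of 0.97 ± 0.12. The malate transporter ALMT1 did not pass the test, at 0.77 ± 0.32. Camera with a preset correlation gave this list an adjusted p of 5.84e-11, and the adjusted p was 0.0358 with an estimated correlation (Benjamini-Hochberg over 28 lists).

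Of 13 tested genes of membrane lipid remodelling, 12 rose, and 13 did when adjusted over the list alone, with a median log2 fold change of 3.51. PLDP2, a phospholipase D, was 45.3-fold higher and NPC4, a phospholipase C, 40.1-fold higher. SQD1 and SQD2, which make sulfolipid, had log2 fold changes of 1.90 ± 0.05 and 1.37 ± 0.16. G3PP2 was not called, at 0.37 ± 0.12. The camera adjusted p was 4.56e-09, and 0.0397 with an estimated correlation. All 9 tested phosphatases and nucleases of the third list rose, over all genes and adjusted over the list alone, with a median of 4.58. The ribonuclease RNS1 was 60.7-fold higher. PAP14 had no count in the libraries labelled wild type and was at least 123-fold higher against a floor of 3 counts over the group. The camera call for this list was lost with an estimated correlation (adjusted p = 0.103, against 1.4e-06 with the preset one).

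The list of Pi regulators, which was not chosen for induction, moved both ways: 9 of 20 rose and 3 fell, with the same counts adjusted over the list alone. PHR1, the transcription factor that activates Pi starvation genes, was at −0.06 ± 0.08 and not called. PHO2, which targets Pi transporters for degradation, rose by 1.25 ± 0.21 and the vacuolar Pi transporter PHT5;1 by 2.09 ± 0.38. HRS1 and its homologue HHO1 fell by 1.55 ± 0.25 and 1.65 ± 0.14, and SPX4, a repressor of PHR1, fell by 0.80 ± 0.12. Camera did not call this list (adjusted p = 0.104).

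Anthocyanin and flavonoid genes were higher: 18 of 20 rose and 2 fell, over all genes and adjusted over the list alone, with a median log2 fold change of 4.52, or 4.23 with groups at 0 set to their bound. DFR, a late enzyme of anthocyanin synthesis, was 102-fold higher, and the activator MYB75 52.5-fold higher, or 83.3-fold without wild type 3. GL3, a bHLH partner of these activators, fell by 0.63 ± 0.15, a call lost without 1 library in 4 of the 6 cases (wild type 1 or 3, vih1vih2 1 or 2, log2 fold changes of −0.60, −0.60, −0.59 and −0.59). EGL3, the other that fell, was at −0.43 ± 0.13, and lost its call when any 1 library except wild type 2 was left out, with log2 fold changes of −0.36 and −0.39 without wild type 1 or 3 and −0.47, −0.40 and −0.42 without vih1vih2 1, 2 or 3. The count that fell was thus 0 without wild type 1 or 3 or vih1vih2 1 or 2, and 1 without vih1vih2 3. The camera adjusted p was 4.56e-09, and 0.0397 with an estimated correlation.

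Jasmonate response genes were higher as well, with 19 of 21 called over all genes and 20 adjusted over the list alone, and a median log2 fold change of 3.73. The lipoxygenase LOX2 went from 123 ± 77.4 to 2943 ± 44.8 CPM, 23.9-fold higher, or 37.4-fold without wild type 3, and the storage protein VSP2 was 13.3-fold higher. JAZ10, a repressor of jasmonate signalling, rose by 4.82 ± 0.22. The camera adjusted p was 4.73e-12, and 0.0357 with an estimated correlation.

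Nuclear photosynthesis genes fell: 22 of 24 were lower, over all genes and adjusted over the list alone, with a median log2 fold change of −1.42. LHCB1.4, a light-harvesting protein of photosystem II, went from 6804 ± 63.7 to 1408 ± 39.0 CPM, and its family's near-identical members may share reads. LHCA1, of the antenna of photosystem I, went from 4354 ± 470 to 1018 ± 1.23 CPM. The camera adjusted p was 7.69e-12, and 0.0445 with an estimated correlation. Beside this, the 50 most counted genes took 22.18 ± 0.145% of counts in the libraries labelled wild type and 12.99 ± 0.179% in those labelled vih1vih2 (two-sided exact permutation p = 0.1, the smallest that 3 against 3 can give).

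Of 14 sulfate deficiency genes, 10 rose, and 11 did when adjusted over the list alone. LSU2 was 15.1-fold higher and SDI1, a repressor of glucosinolate synthesis, 13.3-fold higher. The camera adjusted p was 7.12e-06, and 0.0397 with an estimated correlation.

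For 7 further lists camera gave an adjusted p under 0.05 that was lost with an estimated correlation. Such a loss need not come from correlation between the genes. For the cytokinin list the estimate was −0.0266, below the preset 0.01, yet the unadjusted camera p went from 0.00162 to 0.0306. Of 11 heat shock genes 9 rose, or 10 adjusted over the list alone, among them the regulator HSFA2 with a log2 fold change of 4.52 ± 0.40 (adjusted p = 0.0885 with an estimated correlation). With vih1vih2 1, 2 or 3 left out, 6 heat shock genes rose. Of 9 senescence genes 6 rose, by both counts, among them SAG13, which was 253-fold higher, and the NAC factor ORE1 (0.0885). Without wild type 1, 4 senescence genes rose. Of 18 salicylate defence genes 10 rose by both counts, and 2 fell, or 3 adjusted over the list alone (0.213). Only 1 fell when any 1 library except vih1vih2 3 was left out. PR1, a defence marker, had no count in the libraries labelled wild type and was at least 1005-fold higher. Of 9 type-A response regulators of cytokinin signalling 6 fell and 1 rose, by both counts, with ARR5 at −2.15 ± 0.16 and ARR16 at 1.81 ± 0.14 (0.0885). Of 20 cell division genes 10 fell, by both counts, with the cytokinesis syntaxin KNOLLE at −0.86 ± 0.11 (0.0883). Of 9 sugar starvation genes 5 fell and 1 rose, by both counts, with DIN10 going from 2438 ± 21.3 to 385 ± 59.1 CPM (0.151). Here 3 fell without vih1vih2 2, and the riser, BZIP1, lost its call without wild type 1 or 3 or vih1vih2 1 or 2, so that 0 rose. Of 13 nitrate response genes 5 fell and 1 rose, by both counts, and the nitrate reductase NIA1 was at −2.37 ± 0.05 (0.211). In this list 2 rose without vih1vih2 3, and the camera call itself was lost without wild type 1 or 3 or vih1vih2 1 or 2 (adjusted p = 0.0658, 0.062, 0.0519 and 0.0628).

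The other lists did not pass camera, though the iron deficiency list did without vih1vih2 1 (adjusted p = 0.0496). By fry, every list tested had an adjusted p under 0.05 except the morning clock (0.193) and iron excess (0.139) lists. Fry does not set a list against other genes, and 40.9% of all tested genes were called, so passing it does not single a list out. The root hair list passed fry (adjusted p = 0.00347) with a median log2 fold change of −0.09. Of 21 iron deficiency genes 10 rose and 5 fell by both counts: BHLH100, a transcription factor of the iron response, rose by 4.60 ± 0.10, while FIT, the regulator of iron uptake in roots, fell by 2.29 ± 0.11. Without wild type 1 or 3 or vih1vih2 1 or 2, 3 of the iron deficiency genes fell. Of 19 genes of inositol phosphate metabolism 10 rose, or 11 adjusted over the list alone, and 4 fell. Without wild type 2 or vih1vih2 1 or 2, 7 of them rose. DSP2 and DSP4, of a family of inositol pyrophosphate phosphatases, rose by 3.61 ± 0.22 and 3.61 ± 0.08, and DSP5 fell by 1.80 ± 0.24. In the auxin list, 4 of 12 rose and 6 fell by both counts, and the auxin response repressor IAA29 was at −4.40 ± 0.20. Among 20 genes of the abscisic acid, cold and drought list 10 rose, or 11 adjusted over the list alone, and 5 fell.

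**Figure D2:**
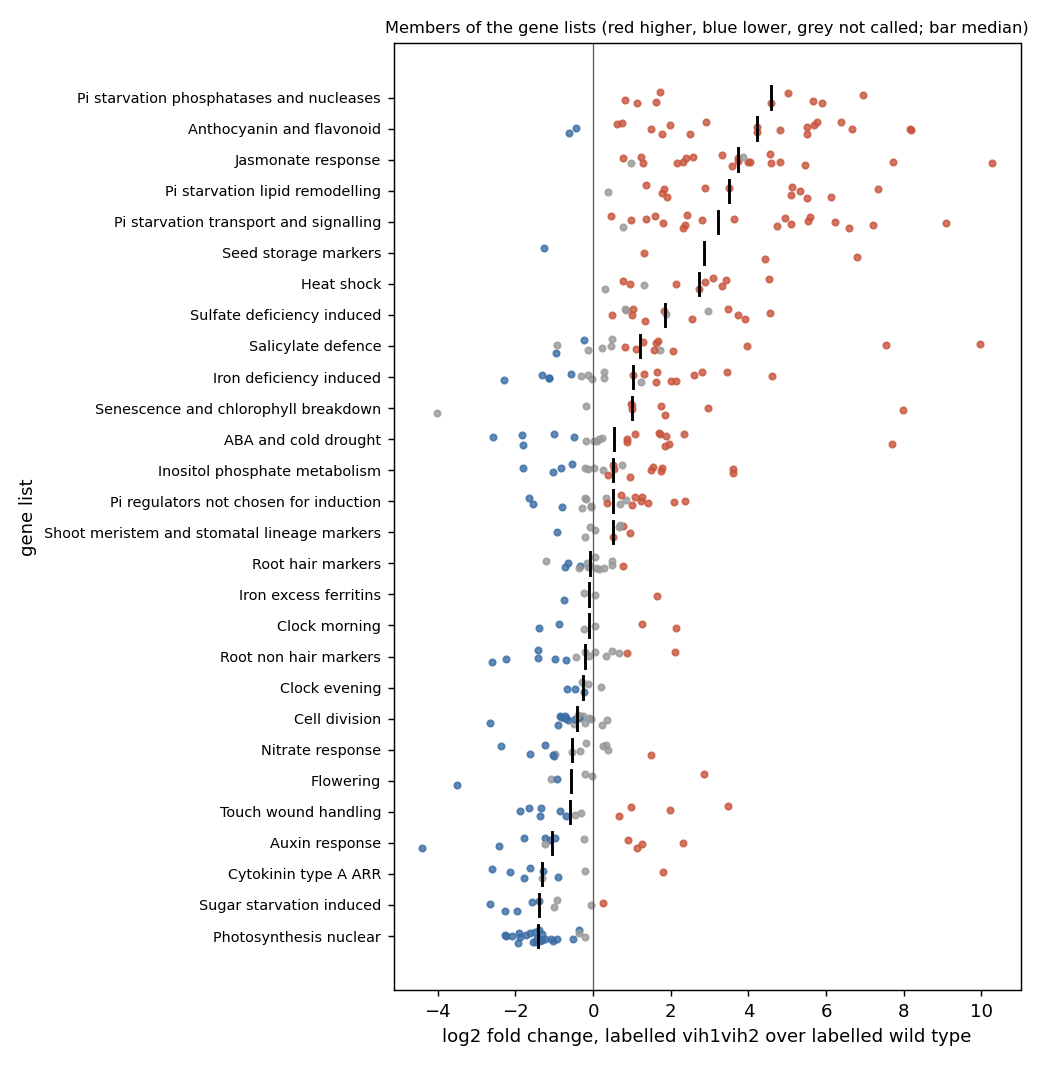
The log2 fold change (labelled vih1vih2 over labelled wild type) of each tested member of 28 gene lists, red where higher, blue where lower and grey where not called, with genes that have no count in a group drawn at their bound and a black bar at the list median. The 3 Pi starvation lists, the anthocyanin list and the jasmonate list lie to the right, and the photosynthesis list, with a median of −1.42, to the left.

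Markers of the organs and cell types in a seedling, and of harvest time and handling, gave these counts. Of 15 root hair markers 1 rose and 3 fell by both counts. Of 15 other root markers 2 rose by both counts, and 6 fell, or 7 adjusted over the list alone, among them the Casparian strip proteins CASP1 and CASP2 at −1.43 ± 0.07 and −2.24 ± 0.18. Only 1 of these other root markers rose without wild type 1 or 3 or vih1vih2 2 or 3, where WOX5 lost its call. Of 9 shoot meristem and stomatal markers 3 rose, or 4 adjusted over the list alone, and 1 fell. Of 4 seed storage markers 3 rose and 1 fell by both counts, and 0 fell without wild type 2 or 3 or vih1vih2 2 or 3. Of 6 flowering genes 1 rose and 2 fell by both counts. The riser, FUL, lost its call when any 1 library except wild type 3 was left out, so that 0 rose, and only 1 fell without wild type 3 or vih1vih2 2. Of 6 morning clock genes 2 rose, including LHY at 2.13 ± 0.23, and 2 fell, by both counts. Of 6 evening clock genes 3 fell, including ELF4 at −0.66 ± 0.07, and 4 did when adjusted over the list alone. Of 12 touch and wound genes 4 rose and 6 fell by both counts. Of 4 iron excess genes 1 rose, 1 fell over all genes and 2 fell adjusted over the list alone.

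Over all 22818 genes tested, 4891 rose and 4433 fell, 40.9% of those tested. The change was at least 2-fold for 2589 that rose and 1695 that fell, counts that became 1585 and 1050 when a gene needed 5 CPM in 3 libraries. In 56.4% of genes the 3 values of one group all lay beyond those of the other, where chance gives 10%. Among genes of at least 5 CPM, the 8 of largest fitted rise had no count in the libraries labelled wild type. Since such fitted values are no bound, these are not shown to have risen most: TAT3, of the jasmonate list, with 4, 4 and 0 counts there, was 1364-fold higher (2077-fold and 906-fold without wild type 2 or 3), above some of the bounds that follow. GSTU3, a glutathione S-transferase, was at least 2454-fold higher. The receptor-like protein RLP32 was at least 1636-fold higher, and ADPG1, a polygalacturonase that separates cells, at least 1390-fold higher. TPS04, a terpene synthase, was at least 807-fold higher. AT1G11925 (Stig1 family), AT2G31425 (a pectin methylesterase inhibitor family member) and AT2G19890 were at least 2366-fold, 1004-fold and 550-fold higher. In the other direction, the polyamine transporter PUT1 had no count in the libraries labelled vih1vih2 and was at least 522-fold lower. Some other genes lacked their counts in single libraries, and a like loss from a whole group was not tested for the genes given with a bound. Each bound holds only if no counts were lost. ATX1, a copper chaperone, went from 127 ± 9.14 to 1.69 ± 0.203 CPM, and AT5G46900, of a lipid-transfer protein family, from 76.8 ± 0.321 to 1.18 ± 0.166 CPM. AT5G62340 was at −7.63 ± 0.92, or −8.22 without vih1vih2 1. AT5G62330 was at −7.59 ± 0.76, with 4 counts in vih1vih2 1 and 0 in the other libraries so labelled. AT3G43850 was at −6.72 ± 0.34. ATCSLB05, of the cellulose synthase-like family, was at −6.05 ± 0.62, or −6.70 without vih1vih2 1, and AT5G54585 at −5.87 ± 0.43, or −6.48 without vih1vih2 2.

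**Figure D3:**
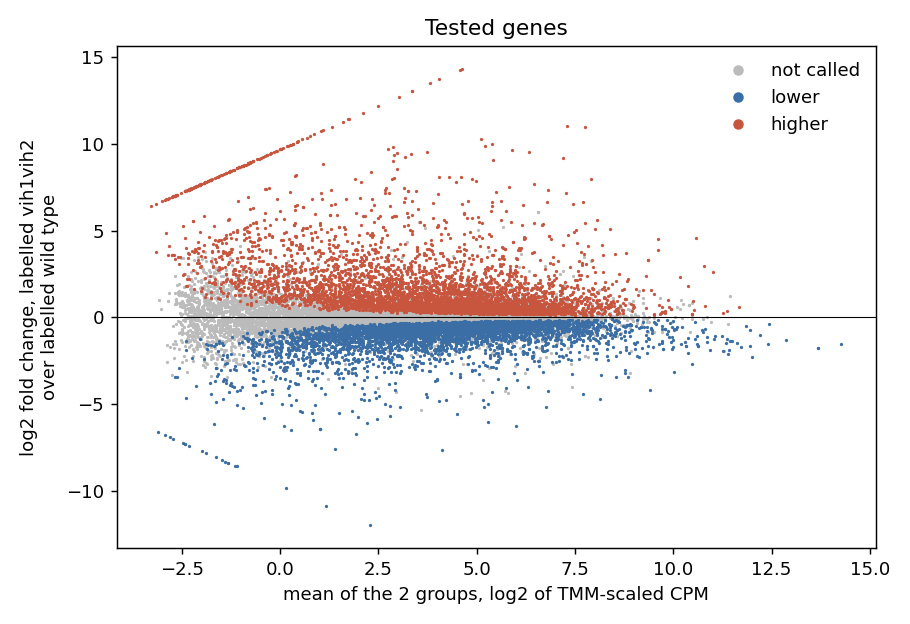
The log2 fold change (labelled vih1vih2 over labelled wild type) of each tested gene against the log2 of its mean TMM-scaled CPM, red where higher (4891 genes), blue where lower (4433) and grey where not called. The straight lines of points at the edges are genes with no count in 1 group, whose fitted fold change is no bound.

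Of the tested rows, 1709 shared all 6 counts with another row, and 342 had a library far from the others of its group. The labels do not say whether the libraries of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical.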

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

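The settings that collapse copied rows, keep malformed rows, remove genes with a gap or moderate robustly were chosen after seeing the data. VIH1 and VIH2 stayed higher in the libraries labelled vih1vih2, past the threshold, under every alternative run for them, with log2 fold changes of 2.203 to 2.474 and 3.536 to 3.720 when each library was left out. The count of Pi starvation genes that rose was 37 to 40 without 1 library, 32 under the filter of 5 CPM in 3 libraries, where fewer were tested, and 41 with DESeq2. Of the 42 tested, 0 were called lower by edgeR's quasi-likelihood test, by DESeq2, by limma-voom or without 1 library, and 0 were lower at an unadjusted p under 0.05, since every fitted log2 fold change was above 0. Without 1 library 4130 to 4377 genes rose and 3684 to 3775 fell, and 2353 to 2534 and 1543 to 1638 did so by at least 2-fold. The stricter filter left 1585 higher and 1050 lower by at least 2-fold, since it tests fewer genes. A threshold of 0.01 left 3136 higher and 2623 lower, and glmTreat against 1.5-fold left 2452 and 1661, both stricter by construction. DESeq2 called 5800 higher and 5329 lower. The share of the most counted genes differed by −9.19 percentage points for 50 genes, by −6.16 for 10 and by −9.99 for 200, and by −9.29 to −9.11 without 1 library. No call among the named genes reversed where it was run: 156 genes in most settings, 125 under the stricter filter and 153 with gap genes removed, while the threshold of 0.01 and glmTreat were run for counts alone. Leaving out 1 library ended 7 to 14 of these calls, limma-voom 3 and no filter 1. The nitrate list lost its camera call under the filter (adjusted p = 0.0502), with the block and in 4 of the 6 cases without 1 library. The iron deficiency list gained one under the filter (0.0171) and without vih1vih2 replicate 1 (0.0496). The cause was not tested. The replicate numbers did not pair the samples: deviations of same-numbered libraries correlated at 0.031, −0.012 and −0.025 across genes, and only number 1 was best with its own. With the replicate block, 3463 genes rose and 3020 fell, 37 of them Pi starvation genes that rose, and 18 named genes were no longer called.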

Other observations

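Small nucleolar RNA genes, which guide the modification of ribosomal RNA, were higher in the libraries labelled vih1vih2. Of 126 distinct rows 97 rose, with a median log2 fold change of 1.81, and 74 to 87 rose without 1 library. Their share of counts was 0.0996 ± 7.81e-05% and 0.193 ± 0.0262% (SD, n = 3, two-sided exact permutation p = 0.1, the smallest possible). The 5.8S rRNA gene AT2G01020 went from 47.5 ± 0.949 to 394 ± 10.098 CPM, and AT3G41979 from 121 ± 4.51 to 1195 ± 22.9 CPM, counts that the row AT3G06355 shares. The 18S rRNA genes AT2G01010 and AT3G41768 rose by 0.64 ± 0.07 and 0.62 ± 0.07 on the log2 scale, and the 4 rRNA genes together took 0.389 ± 0.0221% and 0.809 ± 0.0414% of counts (SD, n = 3, two-sided exact permutation p = 0.1). These genes were chosen after their values were seen, and reads of rRNA copies cannot be assigned to 1 copy.

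Families of 10 or more genes grouped by the stem of their symbol were tested with camera, and 15 of 134 had an adjusted p under 0.05 with a preset correlation. With an estimated correlation these calls were lost, the smallest adjusted p being 0.341, a loss that need not come from correlation between the genes. Of 44 receptor-like proteins (RLP), which sense signals at the cell surface, 27 rose and 4 fell, with a median of 1.11. Of 40 cysteine-rich receptor-like kinases (CRK) 22 rose and 4 fell. Of 15 SAUR genes, which respond to auxin, 11 fell and 2 rose, with SAUR22 at −2.78 ± 0.13. Of 12 PTAC genes, for proteins of the plastid chromosome, 8 fell.

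The tests in the remaining paragraphs were chosen after the result was seen, apart from the comparison of short coding genes and the splits of the samples, which were planned. For the short coding genes, the requirement that a bootstrap interval clear the bound was added after the difference was known. Without it that explanation would have been set aside. The test of poly(A) removal first used plastid genes alone, and mitochondrial genes were added later because plastid transcripts can fall for other reasons. Its bound, at first an upper quartile below 0, which left the explanation open, was then set to a median below that of the snoRNA genes by more than the interquartile range.

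VIH1 and VIH2 had more counts in the libraries labelled vih1vih2. A single mislabelled library or a swap of single libraries is argued against, since the lowest correlation within a group exceeded the highest between groups by 0.095. An exchange of both whole groups cannot be told apart from a true rise. The labels name VIH2 (log2 fold change 3.64) and VIH1 alone as disrupted, and the count of a disrupted gene can stay high. They fix a direction for no other gene. This includes the Pi starvation genes, of which 40 of 42 were called higher in the libraries labelled vih1vih2. Transcription driven from the insertions also stays open: 1 of the 4 flanking genes, AT5G15060, with no count in the libraries labelled wild type and 80, 48 and 56 in the others, lay in the top 1% of genes by change. Its rank rests on a fitted value that is no bound. On the other side of VIH1, AT5G15080 rose by 0.39 ± 0.09. Beside VIH2, AT3G01300 fell by 1.21 ± 0.09 and the snoRNA gene AT3G01316 rose by 3.05 ± 0.76. AT3G01316 had 2, 0 and 3 counts in the libraries labelled wild type and 14, 16 and 18 in the others. Since 97 of 126 snoRNA rows rose, its rise says little about the VIH2 locus. A biological rise of VIH1 and VIH2 transcripts in the double mutant stays open and untested.

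Organelle transcripts argue against weaker removal of RNA without a poly(A) tail as the cause of the whole rise of snoRNA. They would have to rise by about as much, though their levels may differ for other reasons. The nuclear rRNA share goes with it, at 0.389 ± 0.0221% in the libraries labelled wild type and 0.81 ± 0.0414% in those labelled vih1vih2. The median log2 fold change was −0.28 over 44 mitochondrial genes (quartiles −0.68 and 0.64) and −0.55 over 87 plastid genes (quartiles −1.05 and −0.16), below the snoRNA median of 1.81 by more than either interquartile range. A part in the rise cannot be told apart, because the organelle shares of counts moved apart: the mitochondrial share was 1.27-fold higher, going from 0.0225 ± 0.000735% to 0.0286 ± 0.00224%, and the plastid share was 0.784 times as large, against 1.93-fold for snoRNA (SD, n = 3, two-sided exact permutation p = 0.1 for each, the smallest possible). More short molecules kept in the libraries cannot be told apart from a true rise. Coding genes under 400 bp exceeded those of 1000 to 3000 bp by 0.21 in median log2 fold change. The bootstrap interval, over genes and not libraries, was 0.07 to 0.70. It lies below the difference set in advance as a sign of this cause, but does not clear the bound of 0.5. The snoRNA loci had a median length of 93 bp, so coding genes under 400 bp may not stand for them. A change of ribosome synthesis in the double mutant stays open and untested.

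Single libraries lacked the counts of single genes in 346 cases, over 315 genes, such as SAM1, a methionine adenosyltransferase, with 41 counts in 1 library labelled vih1vih2 and 29647 and 27319 in the others. Overlap with another annotated gene is argued against, with an odds ratio of 1.08 and an upper limit of 1.38. Counts moved to a neighbouring identifier may explain some cases, since 9.57% had a gain within 3 positions against 4.13% beside matched genes, but not most, the median share of lost CPM found there being −0.0406%. Assignment to other identifiers or assembled loci stays open, and no biological explanation was tested.

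The labelled groups gave 9324 called genes, and the highest of the other splits of the 6 libraries gave 5. Every other split mixes libraries of both groups, so the difference between the groups adds to the spread within each side. Few calls could then be made, and the contrast of 9324 with 5 does not measure chance. Only 1 of the 10 splits gave as many, the labelled one, and 10 splits are too few for a share under 0.05.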
